A study of Mus musculus with 9 samples.

How the data were processed

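RNA had been extracted with Trizol from whole frozen hearts and labelled with biotin by the Affymetrix whole-transcript sense target assay, per the labels' protocols. The deposited values are 1 normalized expression summary per probe set and array. The scale was read as log2, because the values run from about 1.55 to 14.2 with no negative entry. The authors' log base, background correction, summary and normalization are not given in the sources used here, and Partek is named without role or version in the submitters' processing notes. The 9 columns of deposited log2 values have nearly the same distribution, so they were taken as normalized between arrays and used as they stand; scanner files were not used here. Normalization of this kind can hide a change common to most genes and leaves differences relative to the bulk of the array.

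The value table holds 80202 probe sets, of which 10553 are negative controls and 65956 are mouse transcript clusters. A table pairing probe sets with the platform annotation lists 32750 of them, 30604 with 1 gene symbol and 2146 with several, which were not used; 33206 transcript clusters have no name in that table and were not tested. Symbols were updated through Entrez numbers with a RefSeq gene table of assembly GRCm38.p6, where 22818 matched and 820 symbols changed, and no coordinates were taken from it, since the build of the array design is not given in the sources used here. For a gene with several probe sets, 355 in all, the probe set with the highest mean over the 9 arrays was kept, which left 30142 genes, 18816 of them protein coding. Many deposited values are tied: 18418 genes, or 61.1%, have the very same value on 3 or more arrays and 268 on all 9, a feature of the deposited table whose origin is not given in the sources used here. Tied values narrow the spread of such genes. There is no read depth on arrays, and precision is limited by the number of arrays.

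Arrays were grouped by the treatment in the labels into control (2 arrays), vesicles (3), cells (3) and sham (1), and replicate numbers follow accession order and pair nothing. Titles also carry an experiment number and a VTS number whose meaning is not stated. Differences were fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, with 1 mean per treatment and the experiment as a fixed block. The fit took the 8 arrays of the 3 injected groups, which leaves 4 residual degrees of freedom and gave 1.18 prior degrees of freedom. The contrasts were vesicles against control, cells against control, vesicles against cells, the mean of both treatments against control, and the experiment itself. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all 30142 genes with a threshold of 0.05. Values after ± are standard errors of the fitted log2 difference, and values per experiment are differences from the control array, or the mean of the cell arrays, of that experiment.

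Of 32 gene lists fixed by name, 31 were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and a list of sex-linked genes served as a check of the animals. Camera with an estimated correlation, camera on ranks and fry were alternatives. A list's score on an array is the mean over its members of the log2 value minus that gene's mean over the arrays, and the error of a list mean comes from fitting these scores to the same design. For each list, members were also adjusted over the list alone, which does not correct for the 31 lists examined in each comparison. The lists, models, alternatives and the rule for named genes were chosen before the data were examined, except 3 alternatives added after seeing the data: leaving out genes tied on 3 or more arrays, cell arrays 2 and 3, or vesicle array 3 with cell array 3. The rule for named genes took up to 10 genes per direction past an adjusted p of 0.05 with the same sign in both experiments, filled up by the lowest unadjusted p where fewer passed (5 per direction for both treatments together). It also took up to 4 members with the lowest unadjusted p of each list described, and Nppa, Nppb, Myh6, Myh7, Col1a1, Col3a1 and Postn in any case. Gene models, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors were counted and not named. Genes shown for single arrays (Sftpc, Scgb1a1, Dbp, Arntl, Fos, Nr4a1 and Sln among them) were picked for that purpose after their values had been seen.

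The steps were tested on simulated data with 200 of the 30142 genes changed by known folds, with false calls in 9, 8 and 12 of 29942 unchanged genes for vesicles against control, cells against control and vesicles against cells. Each gene had independent noise at its own residual spread, which ties narrow, and changes were added in full also to dim genes. With 200 genes changed the adjusted threshold is also easier to pass, so recovery may be overstated for the real data. Sham was compared with the control array of its experiment by value only, and lists were placed among 10000 random lists matched on mean level. Shared controls were simulated 100 times. Alternatives covered the block, the normalization, filters on dim genes at the 30th and 50th percentile, the variance model, array weights, the choice of probe sets and arrays, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.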

Results

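Gene expression was measured in whole hearts of immunodeficient nude mice 6 weeks after treatment for chronic heart failure. The hearts had been infarcted by a permanent tie of the left anterior descending coronary artery, and mice whose ejection fraction lay below 50% were treated 3 weeks after the infarct. There were 3 arrays of hearts given extracellular vesicles, the membrane particles that cardiovascular progenitor cells release, and 3 arrays of hearts given the progenitor cells themselves. The control group had 2 arrays of hearts given the culture medium alpha-MEM, and 1 array came from a sham heart, which received needle punctures and no injection. A cell dose was 500000 cells and a vesicle dose what 500000 cells had secreted in 48 hours. The cells were placed at 3 sites around the infarct under echocardiographic guidance, and the labels describe this route for the cell grafts. The sample titles put the sham array, control array 1, vesicle array 1 and cell array 1 in an experiment numbered 9, and control array 2, vesicle arrays 2 and 3 and cell arrays 2 and 3 in an experiment numbered 1. The labels speak of mice and whole hearts, but nothing in them states that each array is a separate animal. P-values for single genes therefore measure only the spread between these arrays. Camera's p-values at the preset correlation set the genes of a list against other genes. They do not measure the spread of the list mean between arrays. The number of arrays limits the precision of every value. Array medians lay between 4.89 and 4.92 on the log2 scale, and on each array between 6378 and 6790 of the 30142 genes exceeded the 95th percentile of the negative control probe sets.

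None of the classical genes of the failing heart passed a test between the injected groups. After vesicles, log2 differences from medium were 0.10 ± 0.071 (SE) for Nppa and −0.067 ± 0.20 for Nppb, the natriuretic peptides released by strained heart muscle, 0.012 ± 0.024 for Myh6 and 0.077 ± 0.089 for Myh7, the adult and fetal myosin heavy chains of the mouse ventricle. After cells, the same differences were 0.0031 ± 0.071, −0.0031 ± 0.20, 0.011 ± 0.024 and −0.046 ± 0.089. The scar collagens Col1a1 and Col3a1 stood at 0.20 ± 0.14 and 0.14 ± 0.12 after vesicles and at −0.047 ± 0.14 and −0.023 ± 0.12 after cells, with 3 vesicle, 3 cell and 2 control arrays. None of these 6 genes passed limma's test, with adjusted p between 0.723 and 0.968 after vesicles. The sign differed between the experiments for Nppb, Myh6 and Myh7 after vesicles and for all 6 genes after cells: after vesicles Nppb was 0.39 from control in experiment 9 and −0.39 in experiment 1. Across 22 genes of the failure and fetal programme the mean was −0.0059 ± 0.085 after vesicles and 0.0051 ± 0.085 after cells (camera adjusted p = 0.531 and 0.65).

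**Figure D1:**
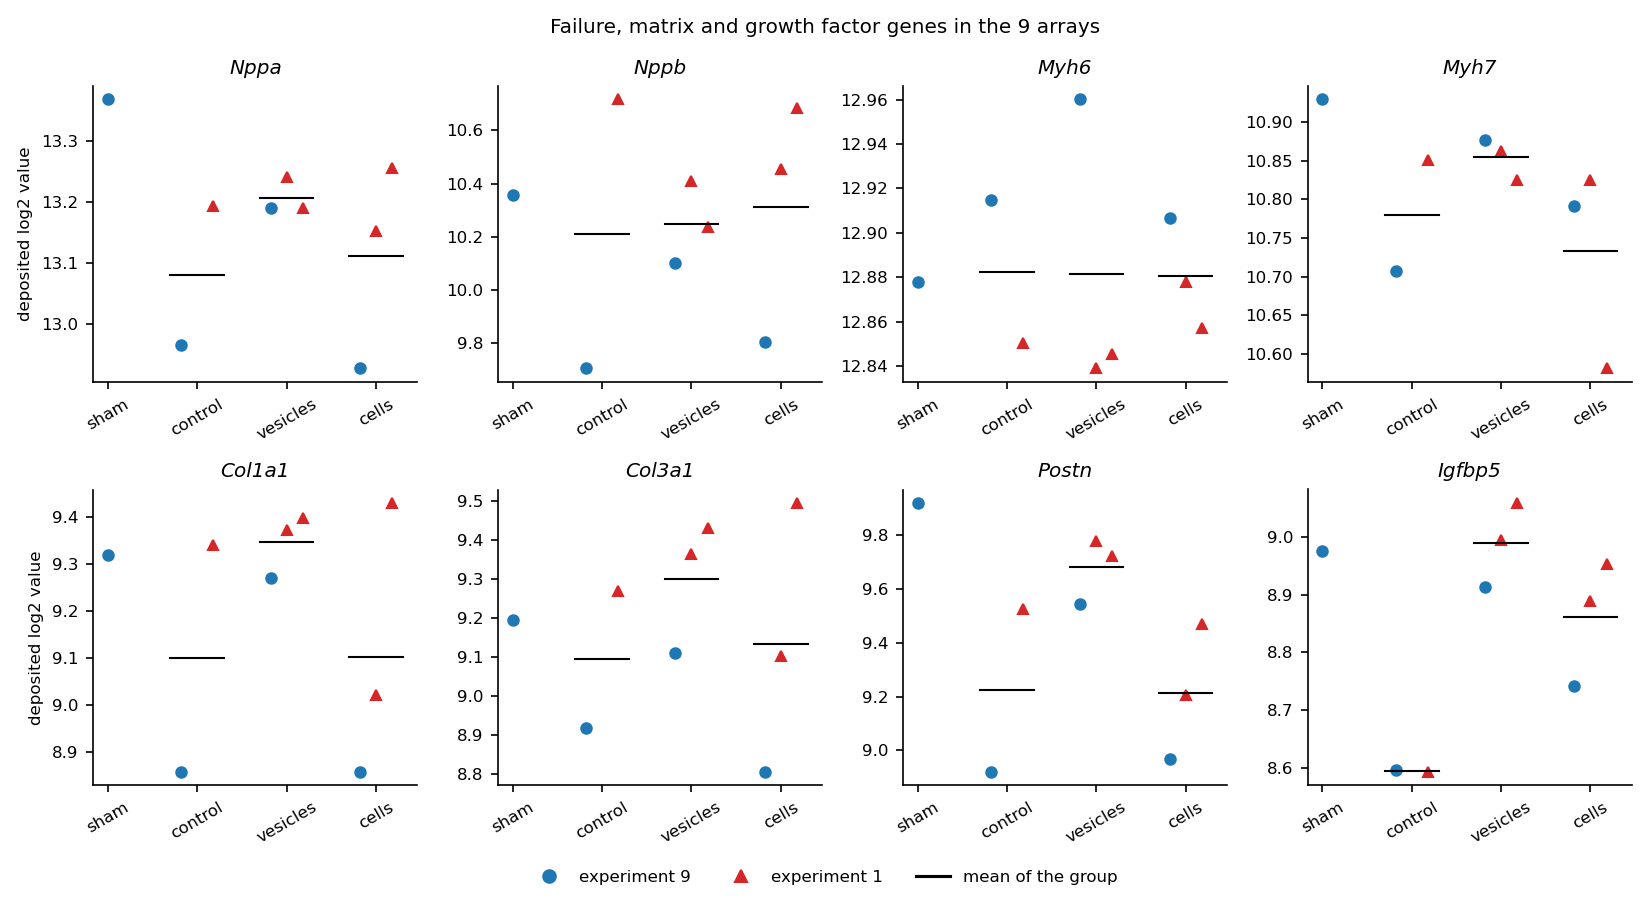
Deposited log2 values of 8 genes on each of the 9 arrays, by group, with circles for experiment 9, triangles for experiment 1 and a bar at the plain mean of each group. Postn lies at 9.54 to 9.78 after vesicles and at 8.97 to 9.47 after cells, while the 2 control arrays lie at 8.92 and 9.52.

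Vesicles were compared with medium to ask what they left in the heart after 6 weeks. Genes of the extracellular matrix were higher as a list after vesicles: 40 of 46 measured members were higher, with a mean log2 difference of 0.14 ± 0.086 (SE over arrays), or 1.10-fold. This call was lost at adjusted p = 0.771 with an estimated correlation. The list score was higher in 3 of 3 vesicle arrays than in the control of the same experiment. Its leading members were Postn, the matricellular protein periostin of activated fibroblasts (0.40 ± 0.12), Mmp2, a gelatinase (0.30 ± 0.12), Lum, the collagen-binding proteoglycan lumican (0.21 ± 0.069), and Col4a2, a basement membrane collagen (0.17 ± 0.046). Mural cell genes were higher too (17 of 20, mean 0.091 ± 0.051; adjusted p = 0.771 with an estimated correlation), led by Pdgfrb, the pericyte receptor for platelet-derived growth factor (0.22 ± 0.065), and Acta2, smooth muscle actin (0.42 ± 0.16). Fibroblast markers (16 of 20 higher, mean 0.073 ± 0.055) and epicardial genes (16 of 17 higher, mean 0.10 ± 0.088), lost alike at adjusted p = 0.771 with an estimated correlation, had values of 0.22 ± 0.10 for Mfap4, an elastic fibre protein, and 0.27 ± 0.13 for Upk3b, a mesothelial marker. The matrix mean was 0.21 in experiment 9 and 0.10 in experiment 1, whereas the epicardial mean of 0.17 in experiment 1 came mainly from vesicle array 3, whose lung transcripts are described below.

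These calls come from camera, limma's competitive gene set test, at a preset correlation of 0.01 between genes. Its adjusted p was 1.5e-11 for matrix, 1.9e-05 for mural cells, 2.5e-04 for fibroblasts and 5.7e-04 for the epicardial list. The correlations estimated for the lists tested ran from 0.045 to 0.744, all above that preset. All 4 calls were lost at adjusted p = 0.771 with an estimated correlation and by fry. No member passed on its own, the lowest adjusted p over all genes and adjusted over the list alone both being above 0.05. Without vesicle array 1 the matrix mean was 0.089, the mural mean 0.057 and the fibroblast mean 0.042, and with the sham array pooled with the controls the matrix mean was 0.044. Without control array 2, which leaves 1 control array assumed to vary like the other groups, the mural (0.052), fibroblast (0.043) and epicardial (0.050) calls ended, and without vesicle array 3 the epicardial call ended at 0.029.

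The fatty acid oxidation list was lower after vesicles, a call lost at adjusted p = 0.771 with an estimated correlation. Of its genes 24 of 29 were lower, with a mean of −0.067 ± 0.027, −0.063 in experiment 9 and −0.068 in experiment 1, and 3 of 3 vesicle arrays below their control. Slc27a1, a fatty acid transport protein (−0.15 ± 0.036), Ech1, a peroxisomal and mitochondrial isomerase (−0.12 ± 0.033), and Acadvl, the very long chain acyl-CoA dehydrogenase (−0.090 ± 0.028), led the list. Oxidative phosphorylation had 43 of 56 members lower (mean −0.027 ± 0.025, camera adjusted p = 0.0714) and did not pass as a list. Within it Cox7a1 and Cox8b, the muscle forms of cytochrome c oxidase subunits, passed adjusted over the list alone at −0.14 ± 0.021 and −0.11 ± 0.015 (adjusted p = 0.0286 for both), but over all genes 0 members passed. The fatty acid call had an adjusted p of 0.037, and no member passed on its own. It held in 10 of 21 settings and ended on leaving out vesicle arrays 1 or 3, control arrays 1 or 2 or cell arrays 1 or 2, with means from −0.072 without vesicle array 1 to −0.045 without vesicle array 3. Its direction turned relative to other genes, at a mean of −0.0054, with the sham array among the controls.

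Several immune lists were lower after vesicles. The hearts came from immunodeficient nude mice, so these lists are not read as amounts of T cells or thymus tissue. T and NK lymphocyte genes were lower as a list (21 of 22, mean −0.10 ± 0.041), as were B lymphocyte genes (18 of 20, −0.050 ± 0.024), thymus and lymphoid genes (10 of 11, −0.18 ± 0.064), cytokine genes (31 of 40, −0.14 ± 0.064) and interferon response genes (30 of 37, −0.23 ± 0.22). Each call was lost, at adjusted p = 0.771 with an estimated correlation, or 0.798 for interferon genes. Cxcl13, a chemokine that draws B cells, had the widest gap at −1.33 ± 0.50. It is a member of both the thymus and the cytokine list, whose medians were only −0.056 and −0.061. Nkg7, a granule protein of cytotoxic lymphocytes, stood at −0.15 ± 0.051. Irf1, an interferon-induced transcription factor, stood at −0.33 ± 0.091 and Gbp2, a guanylate-binding protein, at −0.64 ± 0.24. Against this trend Nfkbia, which encodes the NF-kappaB inhibitor, was 0.28 ± 0.025 and passed adjusted over the list alone (adjusted p = 0.0036) but not over all genes (adjusted p = 0.475). The lymphocyte and cytokine means were near 0 in experiment 9 (−0.0057 for T and NK, −0.0088 for B, −0.029 for cytokines) and lower in experiment 1 (−0.17, −0.081 and −0.22), where control array 2 held the highest T and NK score of the 9 arrays, 0.15. The thymus mean was −0.077 and −0.25, and the interferon mean −0.18 and −0.24. Macrophage (−0.11 ± 0.11, camera adjusted p = 0.262) and granulocyte genes (−0.038 ± 0.018, adjusted p = 0.165) did not pass, and the macrophage mean was 0.022 in experiment 9 and −0.22 in experiment 1.

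Camera gave adjusted p of 6.6e-04 for T and NK, 0.0114 for B, 0.0222 for thymus, 0.0222 for cytokine and 0.0114 for interferon genes. No T and NK, B, thymus or interferon member passed on its own. Without control array 2 the T and NK mean was −0.018, the B mean −0.018, the thymus mean −0.11 and the cytokine mean −0.066, all 4 calls ended and the T and NK and thymus directions turned relative to other genes. The B, thymus and cytokine calls also ended without vesicle array 2 (−0.033, −0.15 and −0.10), the thymus call without vesicle array 3 (−0.18) and the cytokine call without cell array 1 (−0.14). The interferon call ended without vesicle array 2 (−0.094), which had the lowest interferon score of the 9 arrays, −0.46, and also without control array 1 (−0.19) or cell array 1 (−0.21).

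The same test passed 5 further lists. Endothelial genes had 23 of 33 members higher (mean 0.032 ± 0.041), immediate early genes 19 of 26 (0.11 ± 0.22), clock genes 14 of 18 (0.078 ± 0.10), growth factors 21 of 37 (0.030 ± 0.032) and p53 targets 14 of 25 (0.019 ± 0.036). Each mean was smaller than its error between arrays, and all were lost at adjusted p = 0.771 with an estimated correlation, or 0.798 for immediate early genes. Among the growth factors Igfbp5, a binding protein of insulin-like growth factors, was higher in 3 of 3 arrays (0.38 ± 0.049), which passed adjusted over the list alone (adjusted p = 0.0192) and not over all genes (adjusted p = 0.591). Without control array 2 the endothelial mean was −0.028, and without vesicle array 1 the immediate early mean was −0.023 and the p53 mean −0.0099. The growth factor and clock calls also ended without vesicle array 3 (0.027 and 0.073), the growth factor mean was −0.0042 with the sham array among the controls, and the p53 call ended on leaving out any array but vesicle array 2 and on ranks (adjusted p = 0.082).

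No single gene passed between vesicles and medium. Limma called 0 of 30142 genes at an adjusted p under 0.05, the smallest adjusted p being 0.235, and 1942 genes had an unadjusted p under 0.05 (576 higher, 1366 lower) where 1507.1 would by chance at the nominal rate. In simulated data for this comparison 5.8% of 29942 unchanged genes had such an unadjusted p, so the nominal count is somewhat low. With arrays centred on their median the split was 686 higher and 906 lower, without genes under the 50th percentile it turned to 476 and 440, and without control array 2 it was 946 and 1282. Least squares without moderation called 4 genes. The genes with the lowest unadjusted p and the same sign in both experiments, none of which passed, included on the higher side Me1, the cytosolic malic enzyme (0.18 ± 0.024), Cd55, a brake on complement (0.27 ± 0.037), and Cast, the calpain inhibitor calpastatin (0.15 ± 0.022). Kbtbd2 (0.10 ± 0.014), Mpp6 (0.10 ± 0.016), Acap2 (0.089 ± 0.015), Phxr4 (0.27 ± 0.042) and Pcare (0.12 ± 0.020) stood higher as well. On the lower side stood Igkv8-21, an immunoglobulin light chain segment (−0.36 ± 0.040), Serpina6, corticosteroid-binding globulin (−0.14 ± 0.017), Fgfbp3, a binding protein of fibroblast growth factors (−0.12 ± 0.015), Rnf128, a ubiquitin ligase (−0.12 ± 0.017), and Naif1, Mettl24, Slc35e4, Ssxa1 and Cypt2, between −0.19 and −0.14. Of these lower genes only Rnf128 (control mean 7.82) lay above the 95th percentile of the negative controls, 7.18 to 7.28 across arrays. Among the higher genes Pcare (control mean 4.58) lay under it. In simulated data for this comparison, limma recovered 48% of 50 genes changed by a log2 of 0.32, 78% at 0.58 and 84% at 2-fold. These shares may overstate recovery in the real data, since changes were added in full also to dim genes and ties narrow the spread. Without control array 1, which leaves 1 control array assumed to vary like the other groups, 823 genes were called.

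**Figure D2:**
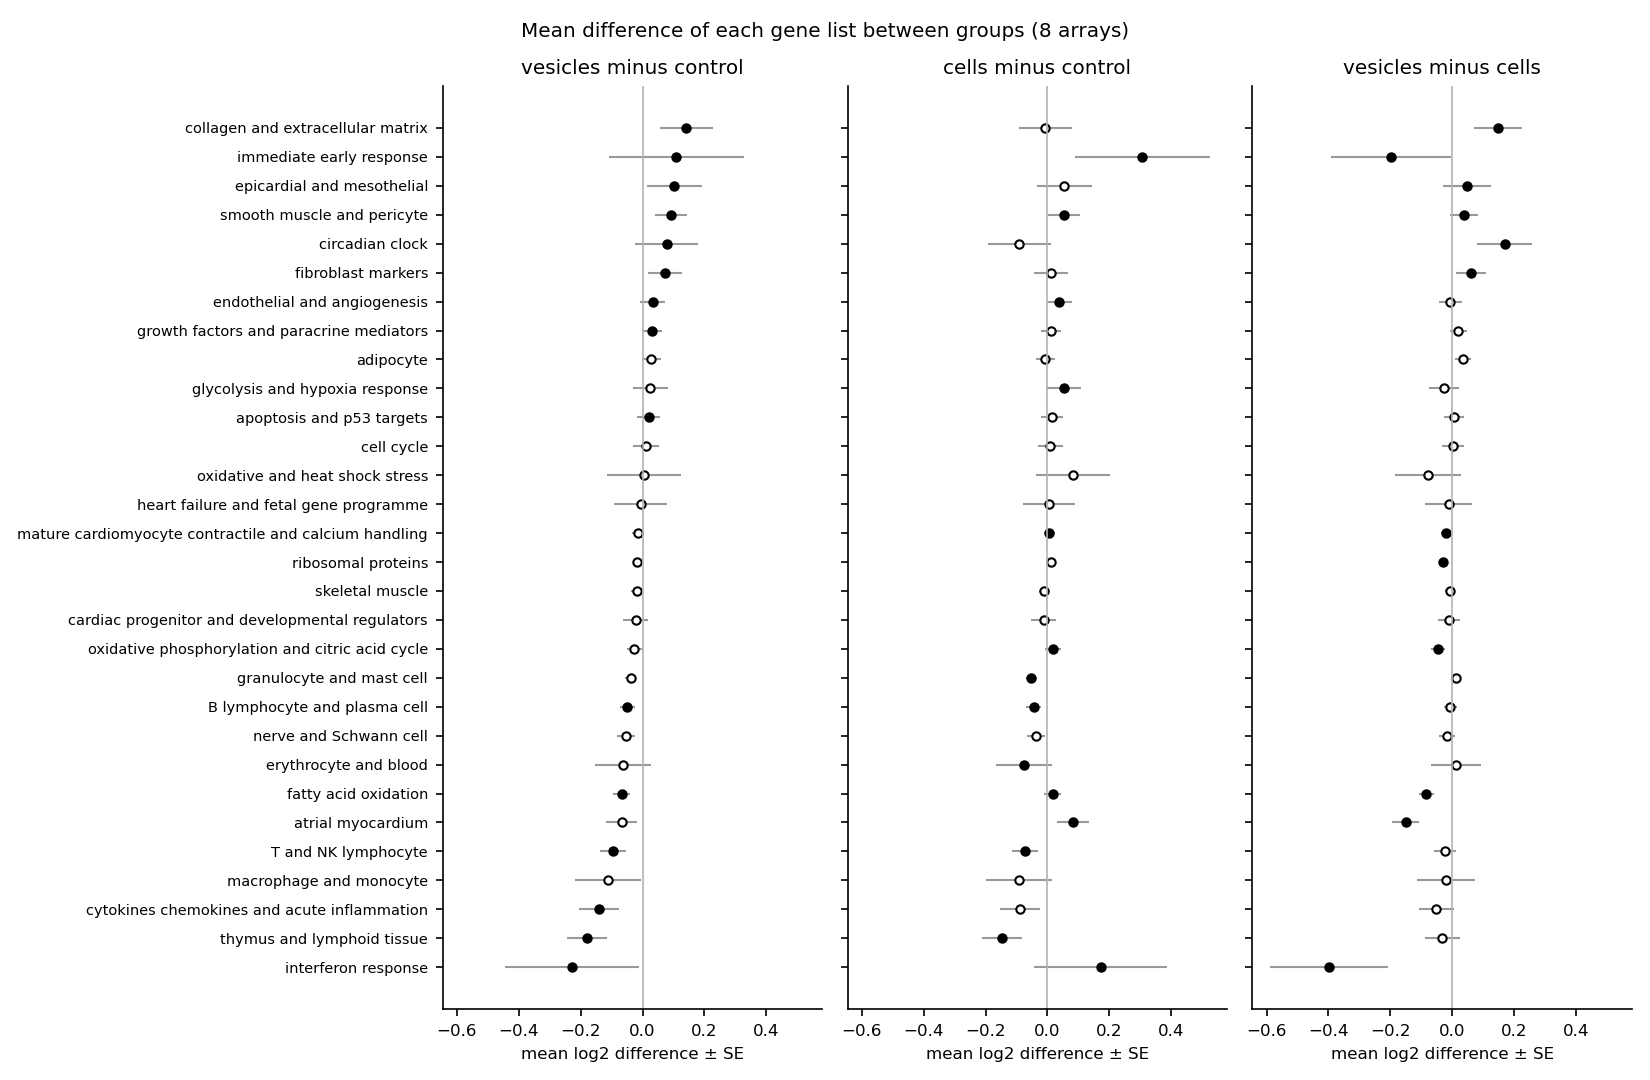
Mean log2 difference of each gene list between groups with its SE over the 8 arrays, for vesicles minus control, cells minus control and vesicles minus cells; filled points passed camera at an adjusted p under 0.05 with the preset correlation, and the lung list is left out. The matrix list lies at 0.14 after vesicles against control and at 0.15 against cells, and interferon genes lie at −0.40 for vesicles against cells.

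Cells were compared with medium in the same way. Immediate early genes, the first genes switched on by a stimulus, many of them transcription factors, were higher as a list after cells. Of its members 22 of 26 were higher, with a mean of 0.31 ± 0.22, or 1.24-fold. Camera's adjusted p of 1.6e-05 was lost at adjusted p = 0.819 with an estimated correlation, no member passed on its own, and 3 of 3 cell arrays lay above their control. Nr4a1, an orphan nuclear receptor (1.04 ± 0.38), Egr1, a zinc finger factor (0.55 ± 0.20), Ccn1, a matrix signalling protein (0.54 ± 0.17), and Klf6, a Krüppel-like factor (0.38 ± 0.093), led the list. The mean was 0.14 in experiment 9 and 0.40 in experiment 1, and cell array 3 held the highest score of the 9 arrays, 0.60, with Fos at 8.14 against 6.11 to 6.70 on the others. The same array held the highest score of the oxidative and heat shock stress list, 0.27. Without cell array 3 the mean was 0.13, and with cell arrays 2 and 3 both left out it was 0.083 and the call ended, in a fit where the lone cell array is assumed to vary like the other groups.

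Matrix genes had no call after cells, with a mean of −0.0064 ± 0.086, an error that does not exclude the shift seen after vesicles, and 18 of 46 members higher (camera adjusted p = 0.655). Genes of the heart muscle cell and its mitochondria lay slightly above other genes: oxidative phosphorylation had 39 of 56 members higher (mean 0.019 ± 0.025), fatty acid oxidation 20 of 29 (0.017 ± 0.027) and the contractile list 23 of 38 (0.0061 ± 0.017). These calls and those below were lost at adjusted p = 0.819 with an estimated correlation. After quantile normalization their directions turned, at means of −0.024, −0.023 and −0.031. Ryr2, the calcium release channel, stood at 0.093 ± 0.023, Crat, carnitine acetyltransferase, at 0.19 ± 0.050, and Tcap, the Z-disc protein telethonin, at −0.44 ± 0.14. Atrial genes were higher (8 of 13, 0.083 ± 0.051), led by Sln, the calcium pump inhibitor sarcolipin (0.50 ± 0.12), and Myl7, the atrial myosin light chain (0.38 ± 0.12). Vascular lists were higher, endothelial with 28 of 33 members (0.039 ± 0.041) and mural with 17 of 20 (0.054 ± 0.051). So were interferon genes (27 of 37, 0.17 ± 0.22) and the hypoxia list (17 of 29, 0.052 ± 0.056). Within the latter Adm, the vasodilator adrenomedullin, stood at 0.32 ± 0.094 and Vegfa, the vascular growth factor, at 0.21 ± 0.089. In experiments 9 and 1 the contractile mean was 0.024 and −0.0074, the endothelial mean −0.055 and 0.11, the mural mean −0.035 and 0.11, the atrial mean 0.019 and 0.12, and the interferon mean 0.047 and 0.25.

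Camera gave adjusted p of 0.00719 for oxidative phosphorylation and endothelial genes, 0.0204 for the fatty acid, contractile, mural and interferon lists, 0.0404 for atrial genes and 0.0454 for the hypoxia list. On ranks the atrial (adjusted p = 0.113) and hypoxia (adjusted p = 0.064) calls were lost. With cell arrays 2 and 3 left out, again a fit with 1 cell array, the atrial mean was 0.00020, the endothelial mean −0.037, the mural mean −0.035, the hypoxia mean −0.0059 and the interferon mean 0.032, and no list passed. Without control array 2 the endothelial mean was −0.022 and 2 lists passed, and without cell array 3 also 2, with a hypoxia mean of 0.0067, while without cell array 2 the interferon call ended at 0.041.

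Lymphocyte, granulocyte, thymus and blood lists were lower after cells. In nude mice the T and NK and thymus lists are again not read as amounts of those cells or that tissue. T and NK genes had 17 of 22 members lower (mean −0.073 ± 0.041), B lymphocyte genes 18 of 20 (−0.044 ± 0.024), granulocyte and mast cell genes 18 of 22 (−0.052 ± 0.018), thymus genes 9 of 11 (−0.15 ± 0.064) and erythrocyte and blood genes 8 of 9 (−0.075 ± 0.090). All 5 calls were lost at adjusted p = 0.819 with an estimated correlation. Cxcl13, a member of the thymus list, stood at −1.09 ± 0.50, and the median of that list was only −0.048. Cd79b, part of the B cell receptor, stood at −0.15 ± 0.043, and Csf3r, the receptor for granulocyte colony-stimulating factor, at −0.12 ± 0.048. Camera's adjusted p lay between 0.0204 for T and NK and 0.049 for thymus genes. These lists lay further below medium in experiment 1 than in experiment 9. The means in experiments 1 and 9 were −0.13 and −0.0063 for T and NK, −0.19 and −0.10 for thymus, and −0.19 and 0.051 for blood genes. Without control array 2, a fit with 1 control array, the T and NK, thymus and blood directions turned relative to other genes. All 5 calls ended there, at 0.0057 for T and NK, −0.012 for B, −0.022 for granulocyte, −0.074 for thymus and 0.089 for blood genes. All 5 also ended without cell array 3, with T and NK at −0.068.

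No single gene passed between cells and medium either. Limma called 0 of 30142 genes, with a smallest adjusted p of 0.479, and 2029 genes had an unadjusted p under 0.05 (506 higher, 1523 lower), while least squares without moderation called 0. The split was 515 higher and 1058 lower with arrays centred on their median, 337 and 553 without genes under the 50th percentile and 897 and 1083 without control array 2. On the higher side Me1 (0.17 ± 0.024), Kbtbd2 (0.10 ± 0.014), Cd55 (0.22 ± 0.037) and Nfkbia (0.17 ± 0.025) came up again, which the shared control arrays favour. Kbtbd2 also had 6 arrays tied at 1 value and Cd55 had 4, and ties narrow the error. With them stood Spry4, an inhibitor of growth factor receptor signalling (0.54 ± 0.085), Apcs, serum amyloid P (0.17 ± 0.027), and Sema6a, Hyal5, Sap30 and Colgalt2, between 0.088 and 0.17. Nfkbia, a member of the cytokine list, passed adjusted over the list alone (adjusted p = 0.0373). That list did not pass camera after cells (adjusted p = 0.0851). On the lower side the lowest unadjusted p belonged to Fgfbp3 (−0.24 ± 0.015, adjusted p = 0.479). It was followed by Naif1 (−0.16 ± 0.016), Mettl24 (−0.21 ± 0.022), Igkv8-21 (−0.27 ± 0.040), Serpina6 (−0.13 ± 0.017), Scd4, a stearoyl-CoA desaturase (−0.36 ± 0.049), the transcription factor Sox12 (−0.17 ± 0.025), and Ssxa1, Eva1b and Tlcd3b, between −0.13 and −0.11. Of these lower genes only Eva1b (control mean 7.59) lay above the 95th percentile of the negative controls, 7.18 to 7.28 across arrays. The control means of Hyal5 (2.74), Apcs (2.89) and Ssxa1 (3.24) lay even under the median of the negative controls, 4.44 to 4.62. Simulated changes were recovered for 38% of genes at a log2 of 0.32, 74% at 0.58 and 94% at 2-fold, shares that may again be overstated. Without control array 1 the count was 901, and with the sham array pooled with the controls it was 1.

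Vesicles were set directly against cells, the comparison named by the study's title. Matrix genes were higher after vesicles in 44 of 46 members (mean 0.15 ± 0.076, or 1.11-fold), in 3 of 3 vesicle arrays against the mean of the cell arrays of the same experiment. The score of cell array 3, 0.16, was as high as those of vesicle arrays 2 and 3, 0.16 and 0.13. This call and those of the mitochondrial lists below were lost at adjusted p = 0.73 with an estimated correlation. Postn stood at 0.47 ± 0.10, Lum at 0.24 ± 0.061, Col5a2 at 0.18 ± 0.056 and Col6a1 at 0.17 ± 0.044, both fibrillar or microfibrillar collagens, and fibroblast markers were higher with them (15 of 20, 0.061 ± 0.049; adjusted p = 0.802 with an estimated correlation). Fatty acid oxidation was lower after vesicles in 28 of 29 members (−0.084 ± 0.024), with Ech1 at −0.18 ± 0.029 and Acaa2, a thiolase, at −0.21 ± 0.060. Oxidative phosphorylation was lower in 47 of 56 members (−0.045 ± 0.022), with Cox7a1 at −0.14 ± 0.018 and Cox8b at −0.12 ± 0.013. Vesicle array 3, whose lung transcripts are described below, held the lowest scores of the 9 arrays on both lists, −0.12 and −0.098. Whether the lung transcripts bear on these lists was not tested. The matrix mean was 0.25 in experiment 9 and 0.10 in experiment 1, and the fatty acid mean −0.072 and −0.089. Camera gave adjusted p of 1.8e-13 for matrix, 6.9e-09 for fatty acid oxidation, 3.5e-09 for oxidative phosphorylation and 0.00943 for fibroblasts. Without cell array 2 the matrix mean was 0.10, without cell array 3 it was 0.22, and without vesicle array 3 the oxidative phosphorylation mean was −0.022, a call that ended at −0.039 with cell arrays 2 and 3 left out. The fibroblast call ended without vesicle array 1 (0.034), cell array 1 (0.018) or cell array 2 (0.044).

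Interferon response genes were lower after vesicles than after cells in 36 of 37 members, with a mean of −0.40 ± 0.19, or 0.759-fold. The call was lost at adjusted p = 0.73 with an estimated correlation, as were those of the atrial and ribosomal lists below. Igtp, an interferon-induced GTPase, stood at −1.78 ± 0.61 and B2m, the light chain of class I histocompatibility molecules, at −0.42 ± 0.12. The mean was −0.23 in experiment 9 and −0.48 in experiment 1, where cell array 2 had the highest score of the 9 arrays, 0.46, and vesicle array 2 the lowest, −0.46. The atrial list was lower in 8 of 13 members, with Myl7 at −0.72 ± 0.11 and Sln at −0.68 ± 0.11 (adjusted p = 0.0079 for both, adjusted over the list alone, and 0.92 over all genes) and a mean of −0.15 ± 0.045, and the call was lost on ranks (adjusted p = 0.177). Ribosomal proteins (15 of 21 lower, −0.030 ± 0.0086) and the contractile list (27 of 38 lower, −0.022 ± 0.015), with Ckm, muscle creatine kinase, at −0.13 ± 0.030, were also lower. Camera gave adjusted p of 2.2e-11, 0.0145, 0.00212 and 0.0342 for these 4 lists, the contractile call being lost at adjusted p = 0.817 with an estimated correlation. The interferon mean was −0.25 without cell array 2 and −0.25 without vesicle array 2, and its call ended at −0.25 with cell arrays 2 and 3 left out. The atrial call ended without vesicle array 2 (−0.12) or cell array 3 (−0.12), and the contractile call without vesicle array 3 (−0.017), cell array 1 (−0.014) or cell array 3 (−0.012).

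The lung, clock, immediate early, mural and epicardial lists also passed between vesicles and cells. Lung genes were higher after vesicles in 14 of 14 members (0.51 ± 0.46, camera adjusted p = 0.00174, adjusted p = 0.817 with an estimated correlation). Nearly all of this lay in vesicle array 3, where Sftpc, the lung surfactant protein C, was 9.75 against 4.28 to 4.52 on the other 7 arrays of the fit, and without that array the mean was 0.024 and the call ended. Clock genes were higher in 13 of 18 members (0.17 ± 0.090, adjusted p = 0.00212, and 0.73 with an estimated correlation), with Dbp, a clock-driven transcription factor, at 0.92 ± 0.33 and Arntl, the clock activator BMAL1, at −0.79 ± 0.27. Dbp was 7.27 and 8.02 on cell arrays 2 and 3 and 8.85 to 9.26 on the other 7 arrays, and without cell array 2 the clock mean was 0.076, while the call held in 21 of 21 settings of array choice, scaling and filter. Immediate early genes were lower after vesicles in 23 of 26 members (−0.20 ± 0.19, adjusted p = 0.0134, and 0.981 with an estimated correlation). The mean was 0.10 in experiment 9 and −0.35 in experiment 1, and −0.0013 without cell array 3, where the direction turned relative to other genes. The call also ended without vesicle array 2 (−0.16) or 3 (−0.15). The mural (0.037 ± 0.046, adjusted p = 0.0239, and 0.858 with an estimated correlation) and epicardial (0.048 ± 0.078, adjusted p = 0.0239, and 0.92 with an estimated correlation) lists stood higher after vesicles by less than their error between arrays. Their signs differed between experiments 9 and 1 (0.14 and −0.012 for mural, −0.052 and 0.10 for epicardial genes). Without cell array 1 the mural mean was −0.012, and without vesicle array 3 the epicardial mean was −0.033.

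**Figure D3:**
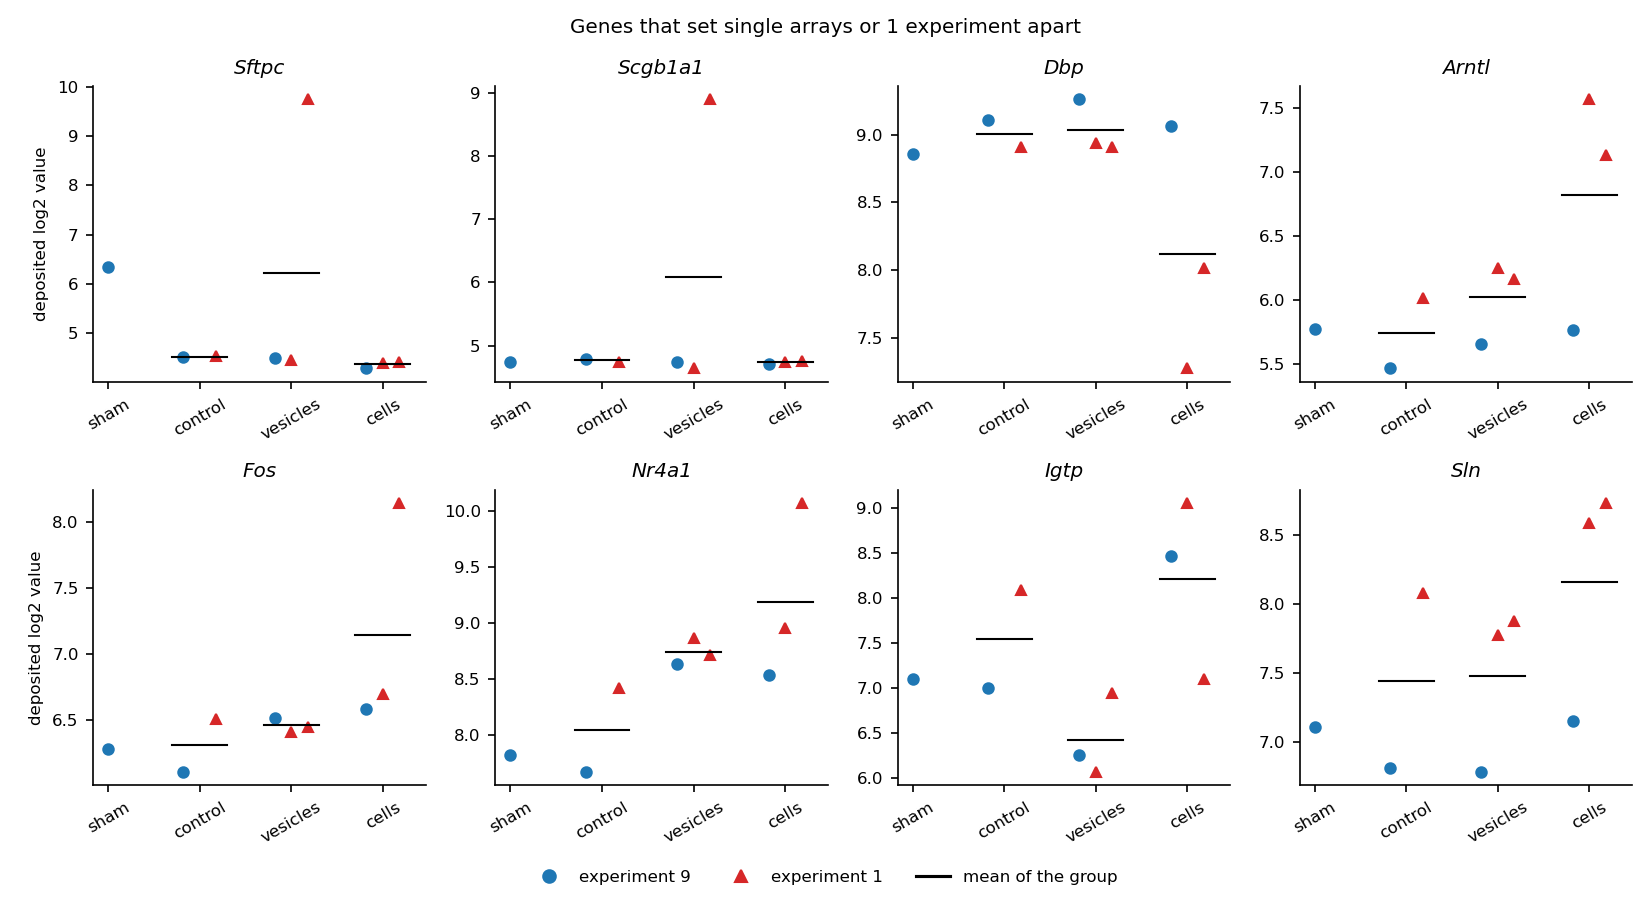
Deposited log2 values of 8 genes on each of the 9 arrays, by group, with circles for experiment 9, triangles for experiment 1 and a bar at the plain mean of each group. Sftpc and Scgb1a1 reach 9.75 and 8.90 on vesicle array 3 alone, Dbp is lowest on cell arrays 2 and 3 at 7.27 and 8.02, and Sln is 6.78 to 7.15 in experiment 9 and 7.78 to 8.74 in experiment 1.

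Limma called 0 of 30142 genes between vesicles and cells, with a smallest adjusted p of 0.823. At an unadjusted p under 0.05 there were 1309 genes (527 higher and 782 lower after vesicles), fewer than the 1507.1 given by chance at the nominal rate. In simulated data 5.9% of 29942 unchanged genes had such an unadjusted p. The split was 689 and 660 after quantile normalization, and least squares without moderation called 0. Genes with the lowest unadjusted p that were higher after vesicles included the splicing factor Srsf2 (0.16 ± 0.015), Itgbl1, an integrin-like secreted protein (0.27 ± 0.028), Plxdc2 (0.40 ± 0.059), F3, tissue factor (0.12 ± 0.018), and Hlf, a clock-controlled transcription factor (0.23 ± 0.034, adjusted p = 0.0159 adjusted over the list alone). Fgfbp3, Pcare, Cast, Acap2 and Crispld1 were higher by between 0.086 and 0.15. Among those lower were Rpl3l, the striated muscle form of a ribosomal protein (−0.13 ± 0.018), and Rnf128, Crybg1, Spint5, Slc35e4, Nop16 and Hyal5, between −0.16 and −0.093. Both group means of F3, Hlf, Fgfbp3, Pcare and Crispld1 lay under the 95th percentile of the negative controls, 7.18 to 7.28 across arrays. So did those of Crybg1, Spint5, Slc35e4, Nop16 and Hyal5. Spint5 (4.08 and 4.21) and Hyal5 (2.76 and 2.86) lay even under the negative control median, 4.44 to 4.62. Simulated log2 changes of 0.32 were recovered for 48% of genes, of 0.58 for 82% and 2-fold changes for 98%, shares that may again be overstated.

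Both treatments together were compared with medium, the contrast with the most arrays. The genes with the lowest unadjusted p lay to the same side of control in 6 of 6 treated arrays, which their choice by this contrast against shared controls favours. Nfkbia (0.22 ± 0.023), Me1 (0.17 ± 0.022), Cd55 (0.25 ± 0.034), Igfbp5 (0.31 ± 0.044) and Kbtbd2 (0.10 ± 0.013) stood higher. In the other direction stood Fgfbp3 (−0.18 ± 0.014), Naif1 (−0.15 ± 0.015), Mettl24 (−0.20 ± 0.020), Ssxa1 (−0.14 ± 0.014) and Igkv8-21 (−0.32 ± 0.036). The control means of all these lower genes lay under the 95th percentile of the negative controls. Differences after vesicles and after cells were close for Me1 (0.18 and 0.17), Naif1 (−0.14 and −0.16), Mettl24 (−0.19 and −0.21) and Ssxa1 (−0.14 and −0.13). They lay further apart for others, as for Fgfbp3 (−0.12 and −0.24), a gap that limma did not call (adjusted p = 0.823). None passed over all genes, the smallest adjusted p being 0.384, while Nfkbia (adjusted p = 0.0059) and Igfbp5 (adjusted p = 0.0277) passed adjusted over the list alone. Limma called 0 genes, and 2296 had an unadjusted p under 0.05 (539 higher, 1757 lower, or 579 and 1079 with arrays centred on their median, 420 and 581 without genes under the 50th percentile and 945 and 1223 without control array 2). Least squares without moderation called 5, and 1237 were called without control array 1. Of the lists, 0.067 for matrix, 0.21 for immediate early, 0.073 for mural, 0.036 for endothelial, 0.079 for epicardial, 0.043 for fibroblast and 0.020 for growth factor genes were higher, all lost at adjusted p = 0.767 with an estimated correlation. Lower means were −0.085 for T and NK, −0.047 for B, −0.16 for thymus, −0.11 for cytokine and −0.045 for granulocyte genes. These 12 lists passed camera with adjusted p from 1.7e-04 for immediate early genes to 0.0471 for granulocyte genes. All were lost at adjusted p = 0.767 with an estimated correlation, and all calls ended without control array 2, where the T and NK mean was −0.0060 and the cytokine mean −0.041. Both directions turned there relative to other genes, as did those of endothelial and thymus genes.

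Whether vesicles and cells moved the same genes was asked of the 2 differences from medium. Across genes, which are not independent replicates, the log2 differences correlated at r = 0.545 with a covariance of 0.00441. Unchanged groups simulated against the same shared controls gave a mean r of 0.607 (0.557 to 0.655 in 100 data sets) and a covariance of 0.00516, so the observed values lay below what shared controls alone give. At an unadjusted p under 0.05, 180 genes were higher and 573 lower in both, against 9.67 and 69.0 for independent lists. The same simulated groups shared 317 genes higher (272 to 374) and 316 lower (280 to 363), so the 573 observed lower lay above the range for shared controls alone and the 180 higher below it. The simulation treats genes as independent, which narrows its ranges, and gives both directions alike, so the overlap is not read as a shared effect. The controls split only into 1 array per experiment, too few for a test. Against different control arrays the correlation was 0.094 for vesicles in experiment 9 with vesicles in experiment 1, −0.014 for cells with cells, 0.015 for vesicles in experiment 9 with cells in experiment 1 and 0.034 for cells in experiment 9 with vesicles in experiment 1. Without genes under the 50th percentile these were 0.145, −0.106, −0.0002 and −0.104. Within an experiment, where the control array is shared, it was 0.252 in experiment 9 and 0.675 in experiment 1. Without cell array 2 the correlation was 0.359, and with cell arrays 2 and 3 left out it was 0.278.

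The experiments were compared with each other across the 8 arrays of the fit. Hearts of experiment 9 had higher mitochondrial and muscle genes than those of experiment 1, with oxidative phosphorylation higher in 55 of 56 members (mean 0.10 ± 0.020), fatty acid oxidation in 27 of 29 (0.12 ± 0.022) and the contractile list in 33 of 38 (0.092 ± 0.014). These calls and those below were lost with an estimated correlation, the smallest adjusted p being 0.322. They had lower matrix genes (44 of 46, −0.26 ± 0.069), macrophage genes (36 of 37, −0.26 ± 0.085), failure genes (18 of 22, −0.24 ± 0.069) and atrial genes (12 of 13, −0.34 ± 0.041). Sln was −1.28 and Myl7 −1.13 between the experiments. Limma called 0 genes (smallest adjusted p 0.212), with 3845 at an unadjusted p under 0.05 and 3 at least 2-fold apart, against 9 each for vesicles and cells against control and 12 between them, while 114 list members passed adjusted over the list alone, among them 38 of oxidative phosphorylation, 14 of fatty acid oxidation and 21 of matrix genes. The experiment was kept as a block in every comparison of treatments. Camera called 20 of 31 lists, from an adjusted p of 6.7e-29 for oxidative phosphorylation.

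**Figure D4:**
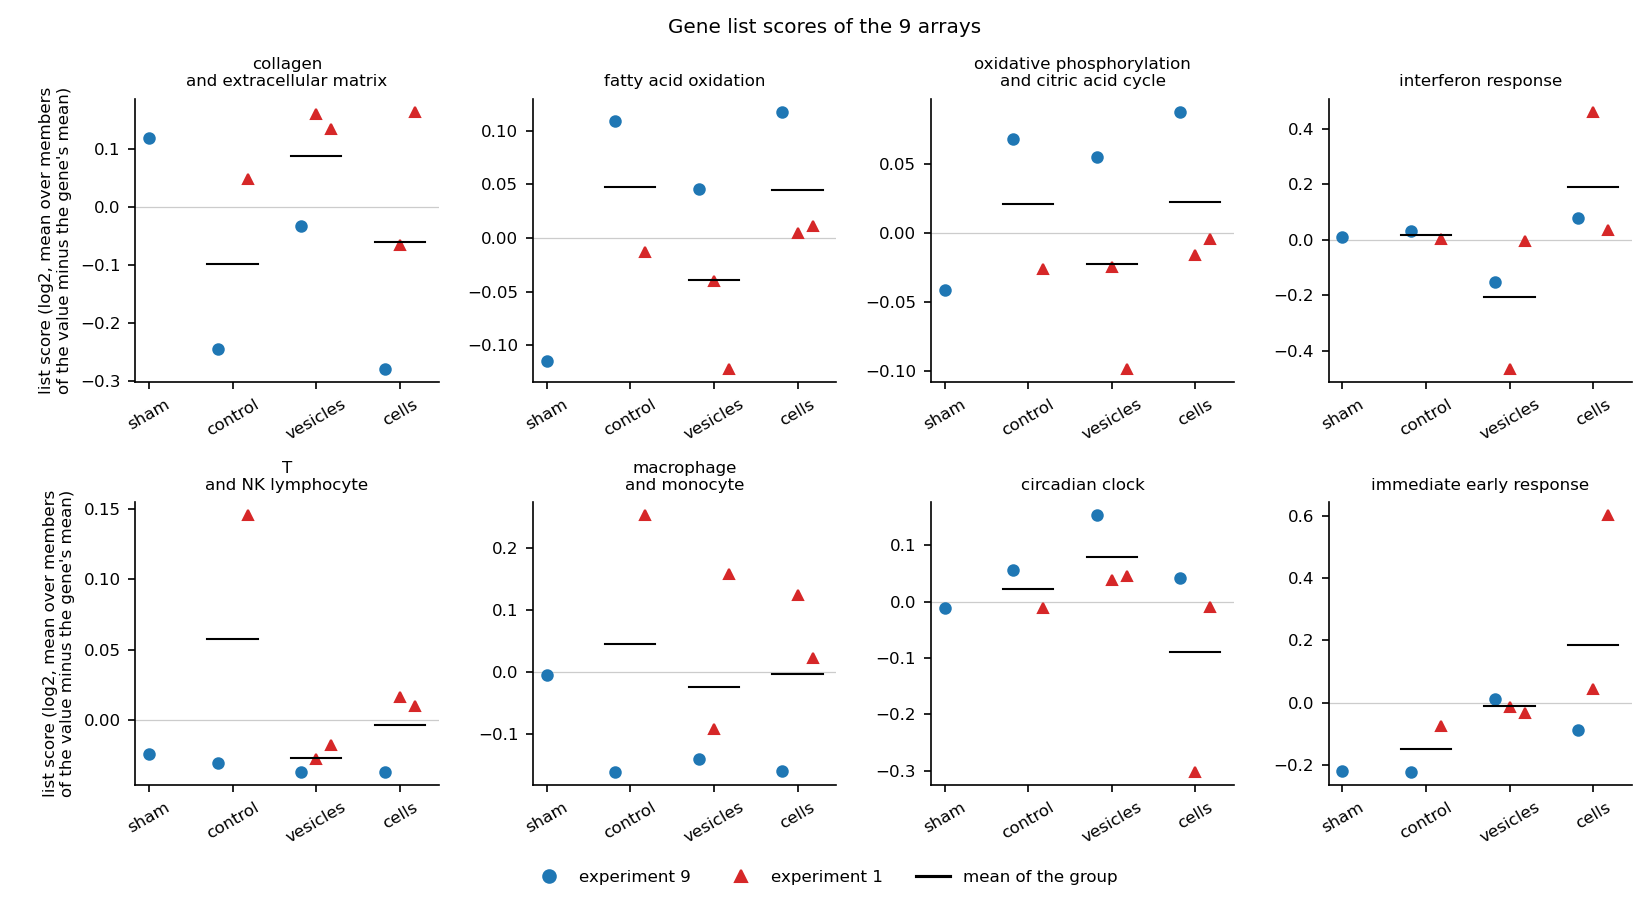
Scores of 8 gene lists on the 9 arrays, each the mean over members of the log2 value minus the gene's mean over arrays, by group, with circles for experiment 9, triangles for experiment 1 and a bar at the plain mean of each group. The matrix score is −0.24 and 0.048 on the 2 control arrays, and control array 2 has the highest T and NK score at 0.15.

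The sham heart, infarcted and pricked without injection, was set against the control array of the same experiment, and with 1 array on each side the differences have no replicate check. In the sham heart 9 genes were at least 2-fold higher and 1 lower, the latter of a kind not named here, against 25 genes at least 2-fold apart between the 2 control arrays. Higher values included Angptl7 (log2 difference 1.33), Thbs4, a thrombospondin of stressed muscle (1.23), Timp4, a metalloproteinase inhibitor (1.18), Col12a1 (1.09) and Postn (0.997), and the lung gene Sftpc (1.84). Lower values included Mylk4, a heart myosin light chain kinase (−0.85), Fbp2, muscle fructose bisphosphatase (−0.84), Ucp3, a mitochondrial uncoupling protein (−0.81), and Id1 (−0.78). The matrix list was higher by a mean of 0.36 and the failure list by 0.22, medians at the 100th percentile of 10000 random lists matched on mean level, while fatty acid oxidation was −0.22 and oxidative phosphorylation −0.11, at the 0th percentile. These percentiles describe the 2 arrays and not the conditions.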

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

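Alternatives changed one choice at a time, and 3 of them, the tie filter and the 2 pairs of left-out arrays, were chosen after seeing the data. Of values of single named genes under other settings, 6560 kept their direction and side of the threshold, 60 moved and 1 became stronger; of list calls 475 kept them, 307 became weaker and 12 reversed. With single arrays left out, 4592 gene values kept them, 70 moved and 50 became stronger, and 307 list calls kept them, 111 became weaker and 14 reversed. No gene was called in the main fits, so a gene value could not become weaker. The gene tallies therefore mostly count genes that stayed uncalled and are no sign of robustness. The matrix calls after vesicles, against control and against cells, held under every setting but the estimated correlation and fry.

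Genes called stayed at 0 except as follows. Without moderation there were 4 for vesicles against control and 5 for both treatments, with sham pooled 1 for cells against control, and at an unadjusted p under 0.05 there were 1942 for vesicles, 2029 for cells, 1309 between them and 2296 for both treatments. Leaving out each array gave 0 to 823 for vesicles, 0 to 901 for cells, 0 to 0 between them and 0 to 1237 for both. Each highest count came without control replicate 1, where the lone control array is assumed to vary like the other groups; the cause was not tested. The count between experiments stayed at 0, and sham differences of 2-fold numbered 10 or 11.

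Lists called, 15 for vesicles, 14 for cells, 13 between them and 12 for both, fell to 0 in each with an estimated correlation and with fry. With the VTS number as a replicate block there were 9 for vesicles and 8 for cells. The meaning of that number, which divides experiment 1 across treatments, is not stated. Under it the fatty acid, p53, growth factor, thymus, clock and immediate early calls ended after vesicles. After cells the hypoxia, T and NK, granulocyte, atrial, thymus and blood calls ended. For both treatments 8 calls held and 4 ended, and between vesicles and cells 12 held and 1 ended. Whether the VTS number marks a batch was not tested. Without genes under the 50th percentile there were 6 for vesicles, 1 for cells and 3 for both, where fewer genes are tested. Quantile normalization ended 6 of the 15 calls for vesicles, 2 of the 13 between vesicles and cells and 6 of the 12 for both treatments. For cells there were 6 without the experiment block, 2 after quantile normalization, 9 without genes under the 30th percentile, 1 without tied genes, 0 without cell replicates 2 and 3 and 7 without vesicle replicate 3 and cell replicate 3. For both treatments there were 6 without tied genes and 2 without cell replicates 2 and 3. Leaving out each array gave 2 to 15 for vesicles, 2 to 17 for cells, 9 to 14 between them and 0 to 14 for both; the cause was not tested.

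Directions, read relative to other genes, reversed for fatty acid oxidation after vesicles with sham pooled (−0.0054), and after cells on quantile normalization for contractile (−0.0312), fatty acid (−0.0227) and oxidative phosphorylation (−0.0237) genes. Without cell replicates 2 and 3, they reversed after cells for glycolysis and hypoxia (−0.0059), endothelial (−0.0369), smooth muscle (−0.0353) and interferon (0.0323) genes, and between vesicles and cells for immediate early genes (0.0483). Without vesicle replicate 3 and cell replicate 3, they reversed for glycolysis and hypoxia after cells (0.0067) and, between vesicles and cells, for epicardial (−0.0330) and immediate early genes (0.0210). With single arrays left out, 14 reversed. Without control replicate 2 these were endothelial, T and NK and thymus genes after vesicles, after cells and for both treatments. Blood genes after cells and cytokine genes for both treatments reversed there too. Without cell replicate 3 hypoxia genes reversed after cells and immediate early genes between vesicles and cells. Without vesicle replicate 3 epicardial genes reversed between them. The cause was not tested.

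Means reached by leaving out each array ran, after vesicles, from −0.0283 to 0.0832 for endothelial, −0.1616 to −0.0178 for T and NK and −0.2393 to −0.1054 for thymus genes. After cells they ran from 0.0067 to 0.0901 for glycolysis and hypoxia, −0.0222 to 0.0893 for endothelial, −0.1382 to 0.0057 for T and NK, −0.2076 to −0.0736 for thymus and −0.2119 to 0.0889 for blood genes. Between vesicles and cells they ran from −0.0334 to 0.1006 for epicardial and −0.3212 to −0.0013 for immediate early genes. For both treatments they ran from −0.0253 to 0.0863 for endothelial, −0.1499 to −0.0060 for T and NK, −0.1767 to −0.0405 for cytokine and −0.2234 to −0.0895 for thymus genes.

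The correlation of 0.545 between the 2 effects was 0.278 without cell replicates 2 and 3 and ran from 0.359 to 0.774 on leaving out each array. Across experiments it was 0.0937 for vesicles, −0.0141 for cells, 0.0152 for vesicles in experiment 9 with cells in experiment 1 and 0.0336 for the reverse; without genes under the 50th percentile these 4 were 0.145, −0.106, −0.0002 and −0.104. Signal limits these results, since 6378 to 6790 genes per array exceeded the 95th percentile of negative controls.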

Other observations

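The tests of vesicles in each heart, of time of day and of cells in each heart were chosen after the result was seen, and the other 5 were written before their values were computed but after list scores per array had been seen.

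Some groups of genes had no call in any comparison of treatments. After vesicles and after cells the list means were −0.11 and −0.093 for macrophage, 0.011 and 0.0085 for cell cycle, 0.0042 and 0.083 for stress, −0.022 and −0.012 for progenitor, 0.028 and −0.0069 for adipocyte, −0.018 and −0.0099 for skeletal muscle and −0.053 and −0.036 for nerve genes. On cell array 3 the stress score was 0.27, the highest of the 9 arrays, alongside the immediate early score of 0.60. Eif2s3y was 6.70 on control array 1 and 6.91 to 7.43 elsewhere, Uty 6.46 against 6.98 to 7.21, and Xist 3.92 to 3.97 on all arrays.

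Vesicle array 3 carried lung transcripts, and lung tissue in that sample may be their source. Of 15 lung genes outside the fixed list, 13 lay above the mean of the other 8 arrays there, and the median difference of 0.32 over the 15 lay at the 100th percentile of matched random lists. An effect of vesicles in each heart is argued against by the lung score of vesicle arrays 1 and 2, which stood at −0.033 from control, where array 3 stood at 1.45. The sham heart, at the 96.4th percentile with a median of 0.013, showed less. Lung tissue was not seen directly and remains a possibility.

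Clock genes on cell arrays 2 and 3 could reflect the time of day at which hearts were taken. On both arrays the mean of 3 activator genes lay above, and the mean of 6 output genes below, the range of those means on the 6 arrays of other groups, by at least 0.40. An effect of cells in each heart is left undecided, because the index of cell array 1, −0.57, lay within the range of those arrays, −0.67 to −0.12, and is 1 array. Sampling times are not given in the sources used here.

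White blood cell genes were high on control array 2, which may mean more white blood cells in that sample. In 18 of 18 leukocyte genes outside the lists the value lay above the mean of the other 4 arrays of experiment 1, with a median of 0.15 at the 100th percentile of matched random lists. The T and NK median lay at the 99.99th percentile of such lists. That list was picked after its high score on this array had been seen, and random lists draw genes independently. The percentile therefore cannot decide whether raised values of dim genes play a part. The dimmer genes as a whole did stand 0.021 higher at the median, and the B lymphocyte median lay only at the 94.6th percentile. More white blood cells would lower these genes in both treatments against medium without any effect of treatment.

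The vesicle and cell arrays were also split in the 9 other ways into 3 and 3. The real grouping called 0 genes, so as many were called in 10 of 10 splits by construction, the highest elsewhere being 1, and this count tests nothing. Lists called were as many in 4 of 10 splits, 13 in the real grouping and up to 19 elsewhere. Splits with vesicle array 1 and cell array 1, both of experiment 9, in the same group are unlike the real design. They called 7, 9, 19 and 8 lists, and the split with 1 gene called was among them. The other splits, balanced like the real grouping, called 3, 19, 12, 18 and 12 lists. With 10 splits no share under 0.05 can arise, so these splits leave open whether the 13 lists reflect treatment or might come from chance.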
